A study of Mus musculus and Homo sapiens with 42 samples.

How the data were processed

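The series measured reverse transcription termination and mutation at each base of 7SK and Xist after chemical probing. The authors deposited a single table for all libraries, with a row for each library, reverse transcription primer and template base. Per the submitters' processing notes, cutadapt and Bowtie2 were used, and their versions, order and settings are not given in the sources used here. Handling of duplicate reads and the genome build are also not given. Per the file headers, the table gives the number of cDNAs that stop at a base and the count of cDNAs that extend through it, as the authors deposited them, without normalization. It also gives the deposited sequencing coverage at the base and the counts of substituted bases. The mutation fraction deposited by the authors equals the substituted calls divided by that coverage.

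The table numbers 42 libraries within 5 experiments, as many as there are labelled samples, and its names give no treatment. Libraries are named here by experiment and by that number. They were assigned to no treatment, group or replicate, since order and values were not used as evidence. The 27 treated, dose and reagent comparisons fixed before the data were examined, with their count model over libraries, were therefore not made, and no SD or n over libraries is given. The statistics below were chosen after the table was seen. The base class of carbodiimides (uridine and guanosine), the regions, the coverage minimum and the positions left out at the ends had been fixed before. The planned rule for named positions needs treated libraries, so the 10 positions with the largest range in each experiment are named in its place. 4 further sets of rows, 2984 in all, carry no library name and were not used.

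Termination rates were computed as stops divided by the sum of stops and extensions, per 1000 cDNAs. The rule fixed before the data for placing stops needs the DMS libraries and could not be applied, so the deposited coverage was used in its place. Base calls fall in number just past the last copied base. At 863 position values where stops exceeded 2% of extensions, the fall between a base and its neighbour towards the primer was a median 0.9455 times the stops given at the base. A value near 1 there means that the base was not copied. The fall on the other side, which would be near 1 had it been the last copied base, was a median 0.186 times the stops, and the former was nearer to the stops in 93.2% of cases. Stops were therefore taken to lie on the base that was not copied, no shift was applied, and the other placement is an alternative. A position was tested with at least 100 cDNAs in every library, outside the 3 bases nearest the 5′ end and at least 80 nt from the primer coordinate, since short cDNAs near the primer are nearly absent. Each experiment except Xist in vitro has 2 primers. For 7SK the primer nearer the 3′ end, at nt 262, was the main one. The other 7SK primer, at nt 154, tests nucleotides 4 to 74 only. For Xist in cells the primer nearer the 5′ end, at nt 396 of the listed sequence, was the main one. It shares 134 tested positions with the other, at nt 622. Reads assigned to no primer, between 0.0330% and 0.676% of terminations, were left out.

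For each position the highest minus the lowest rate over libraries was taken, and the mean range of 200 binomial simulations with the pooled rate and the real coverage in every library was subtracted. Such a range mixes differences between treatments, replicates and preparations. Medians of these ranges were compared between bases, and between predicted unpaired and paired positions, by two-sided permutation tests with 100000 resamples. Benjamini-Hochberg adjustment covered 15 base comparisons and 10 structure comparisons, with a threshold of 0.05. For each alternative its p replaced the main one in that family, and the other main p-values were kept. No adjustment covered the alternatives together, so a threshold gained under a single alternative is weak evidence. Groups of fewer than 10 positions were not tested. Base composition of the 20 top positions was tested with Fisher's exact test, adjusted over 20 tests. Secondary structure was the minimum free energy structure of the whole sequence in the table from RNAfold (ViennaRNA 2.7.2) at 37 °C, without lone pairs. Intervals for single rates are 95% Wilson intervals. Mean rates have 95% normal intervals, and the interval of a ratio of mean rates comes from binomial resampling.

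Nucleotides of 7SK are numbered from 1 at the RNA's 5′ end and those of Xist by the start given in the labels. The 7SK sequence listed for the in vitro libraries and the one listed for cells, each of 332 nt, were aligned with Biopython 1.88. They had 330 identical aligned bases and 1 mismatch, and 1 base of each had no partner. Numbers therefore differ by 1 only from nucleotide 163 to 246 of the cell sequence. The table's target names are h7SK in vitro and 7SK in cells, while the labels give mouse for all samples, and the origin of the in vitro template is not stated there. The study as a whole is listed under mouse and human. Comparisons of 7SK in vitro with 7SK in cells may therefore set a human RNA against a mouse one. Gene identifiers come from the RefSeq gene table of GRCm38.p6, and no genome coordinates are given because the table names no build. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

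The range and its test were tested on simulated counts with the real coverages, 100 simulations per experiment. With no change, the unadjusted p for uridine fell under 0.05 in 7% of simulations for Xist in vitro, 3% for 7SK in vitro, 5% for series A, 7% for series B and 13% for Xist in cells. The test was thus too liberal at the depth of Xist in cells. These simulations gave every library the same rate and varied counts only. They do not show how the test behaves when rates differ between libraries in proportion to their level. With 20 uridines raised 3-fold in 2 libraries, the 20 largest ranges held 96.8%, 86.6%, 90.7%, 97.4% and 75.4% of them in the same order of experiments. Alternatives changed the coverage minimum, the ends left out, the base to which stops are assigned, the structure model, the scale, the subtraction of counting error, the primer distance, the primer and the libraries included.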

Results

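Chemical probing of RNA reads out which bases are open to a small reagent. A modified base stops reverse transcriptase or makes it misread, so cDNA ends collect at the base. EDC and CMC are water-soluble carbodiimides that react with uridine and guanosine where their pairing face is free. Dimethyl sulfate (DMS) reacts with the pairing face of adenosine and cytidine, and glyoxal with that of guanosine. The series asked how these reagents mark 2 structured RNAs, 7SK and Xist, in the test tube and in cells. 7SK is a small nuclear RNA that holds the transcription elongation factor P-TEFb in an inactive complex (mouse gene Rn7sk, gene identifier 19817). Xist is the long non-coding RNA that coats the inactive X chromosome (gene identifier 213742).

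The labels describe 42 samples in 21 groups of 2. RNA made by in vitro transcription was left untreated or treated for 20 min with 10 mM CMC or 100 mM EDC, in 6 samples of 7SK and 6 samples of Xist nucleotides 4701 to 5001. The other samples came from female mouse embryonic fibroblasts (MEF). Series A of 7SK in cells has 8 samples, untreated or treated with 10 mM CMC or 100 mM EDC for 30 min or with 0.5% DMS for 5 min. Series B has 12 samples, untreated or treated with 30 or 90 mM CMC or 300 or 1500 mM EDC for 30 min or with 50 mM glyoxal for 15 min. Xist in cells, from nucleotide 4658 on, has 10 samples, untreated or treated with the same carbodiimide doses as series B. The table of values numbers its libraries within each of these 5 experiments, and the number of libraries equals the number of samples in each. The labels give mouse for all samples, while the study as a whole is listed under mouse and human. The table's target name for the 7SK in vitro libraries starts with an h that the name used for cells lacks, and the origin of that RNA is not stated. No label used here pairs those numbers with treatments, so treated and untreated libraries were not compared. Values below are given as the range and median over the libraries of an experiment, or as comparisons between bases and positions.

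As a ratio of highest to lowest library, depth differed most for Xist in cells. Terminations per library with the primer used here ranged from 427412 to 1047266 for Xist in vitro and from 42201 to 58421 for 7SK in vitro. They ranged from 13728 to 66523 in series A, from 21469 to 176571 in series B and from 2239 to 43477 for Xist in cells. The termination rate at a position is the number of cDNAs that end there per 1000 cDNAs that reach it. Intervals cover counting error only, since amplified reads are not independent molecules.

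In every experiment except series A, the mean termination rate at uridine had the widest range over libraries of the 4 bases, as highest minus lowest. That held at the higher carbodiimide doses of series B and Xist in cells and at the lower doses in vitro. In series B the mean rate over 40 uridines ran from 1.47 to 11.8 per 1000 over 12 libraries, with a median of 3.28. The rate at adenosine ran from 1.38 to 3.73, at cytidine from 1.14 to 3.24 and at guanosine from 1.35 to 3.84. For Xist in cells the mean over 104 uridines ran from 6.80 to 27.5 per 1000 over 10 libraries, against 3.80 to 9.76 for adenosine, 5.35 to 11.9 for cytidine and 5.34 to 8.52 for guanosine. In Xist in vitro the uridine mean ran from 7.21 to 17.8 per 1000 the adenosine mean from 5.55 to 8.87, the cytidine mean from 12.6 to 17.0 and the guanosine mean from 5.59 to 7.81. For 7SK in vitro the uridine mean ran from 15.9 to 28.0 per 1000, of which U63 alone gave a large part: without it the uridine mean ran from 4.11 to 16.8. The other bases there ran from 4.09 to 5.67 for adenosine, 5.99 to 8.02 for cytidine and 3.63 to 7.52 for guanosine. As a ratio guanosine varied more (2.07 times) than uridine with U63 (1.76 times), but less than uridine without U63. In series A, which holds the DMS samples, adenosine had the widest range. It ran from 0.388 to 9.84 per 1000 and cytidine from 0.430 to 5.13, against 1.27 to 4.36 for uridine and 0.397 to 2.27 for guanosine. The adenosine and cytidine maxima were those of library 2, and the next highest values were 3.94 and 1.98 per 1000.

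**Figure D1:**
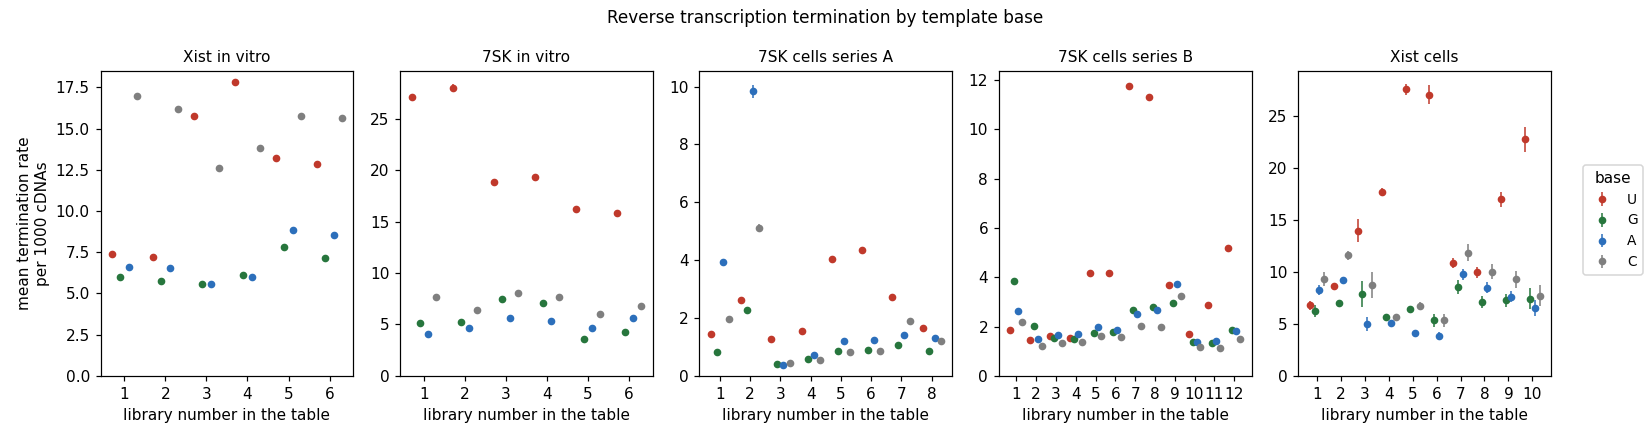
Mean termination rate per 1000 cDNAs (vertical axis) at each template base, for each library of the 5 experiments (horizontal axis, numbered as in the table). Bars are 95% intervals for counting error, and the uridine means of series B span 1.47 to 11.8.

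The same contrast was made position by position. For each position the range of the rate over libraries was taken, less the range that counting error alone would give. In series B the median range at uridines was 7.41 per 1000 (40 positions), against 1.52 at adenosines and cytidines (85 positions), a difference of 5.89. A two-sided permutation test gave p = 1e-05, the smallest that 100000 resamples can give, and 3.75e-05 after Benjamini-Hochberg adjustment over the 15 base comparisons. For Xist in cells the medians were 12.4 per 1000 at 104 uridines and 7.00 at 160 adenosines and cytidines (permutation test, adjusted p = 3.75e-05). For 7SK in vitro they were 4.19 at 39 uridines and 2.17 at 85 adenosines and cytidines (permutation test, adjusted p = 0.006). Xist in vitro showed no difference past the threshold, with 2.33 at 62 uridines and 2.00 at 63 adenosines and 45 cytidines (permutation test, adjusted p = 0.602). On a log2 scale that difference was 0.17, past the threshold (permutation test, adjusted p = 0.00825), and without library 1 it was -0.00742. In series A uridines had 2.78 and adenosines and cytidines 4.36 (permutation test, adjusted p = 0.160). That difference of -1.58 changed sign without library 2 (0.768) and with the other primer (2.30), which tests nucleotides 4 to 74 only. On a log2 scale the series A difference was -1.32, past the threshold (permutation test, adjusted p = 3e-05). The Xist difference in cells was 5.41 per 1000 and, on a log2 scale, -0.03 (permutation test, adjusted p = 0.847). With the other primer, which shares 134 tested positions with the main one, it was 11.5. In simulations of Xist in cells with no change 13% had an unadjusted p under 0.05. Had stops been placed on the last copied base, the differences in series B, Xist in cells and 7SK in vitro would have been 0.307, 1.29 and 0.352 per 1000, none past the threshold. In Xist in vitro it would have been -0.129, and in series A 2.30, past the threshold.

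Guanosine, the other base named for carbodiimides, did not exceed adenosine and cytidine past the threshold in any of the 5 experiments, with stops placed as in the table. With stops on the last copied base it did in 7SK in vitro (2.16 per 1000), series A (1.41) and series B (1.44), where permutation tests gave adjusted p of 0.00057, 0.0415 and 0.00279. The deposited coverage, however, was nearer to the placement in the table at 93.2% of the position values checked. In series B the median range at guanosine was 1.41 per 1000 at 54 positions (permutation test, adjusted p = 0.782), although series B includes glyoxal as well as carbodiimides. Without library 9 of series B the difference was 0.491 per 1000, past the threshold (permutation test, adjusted p = 0.0415). For 7SK in vitro it was 2.25 (adjusted p = 0.847, permutation test), for Xist in vitro 1.13 (adjusted p = 0.160, permutation test) and for Xist in cells 6.85 (adjusted p = 0.847, permutation test). In series A it was 1.28 against 4.36 at adenosines and cytidines, a lower value (permutation test, adjusted p = 3.75e-05). Without library 2 of series A that difference went from -3.08 to -1.12 per 1000, and with the other primer it was -1.22. For uridine and guanosine together, the class fixed before the data were examined, the range was higher than at adenosine and cytidine in series B (2.40 against 1.52, permutation test, adjusted p = 0.0303) and in Xist in cells (10.1 against 7.00, permutation test, adjusted p = 0.00447). The series B difference of 0.878 was 1.61 without library 9, and on a log2 scale the Xist difference was -0.024 (permutation test, adjusted p = 0.888). It was lower in series A (1.52 against 4.36, permutation test, adjusted p = 3.75e-05), where the primer nearer the 5′ end gave a difference of -0.91 with an adjusted p of 0.395, where leaving out library 2 gave -1.02, and where stops on the last copied base turned the difference from -2.85 to 1.68 (permutation test, adjusted p = 0.006). For Xist in cells that placement gave 1.57, short of the threshold. The in vitro experiments did not pass for this class (adjusted p = 0.202 for 7SK and 0.847 for Xist, permutation test). The 7SK difference of 0.734 did pass in the permutation test without library 1 (1.13, adjusted p = 0.0118), without library 6 (1.07, adjusted p = 0.0355) and on a log2 scale (0.33, adjusted p = 0.00354), and with stops placed on the last copied base (1.62). Positions of one RNA are not independent replicates, so these p-values describe how bases are distributed along these RNAs.

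The bases at the top of each list were counted as well. Of the 20 positions with the largest range in series B, 18 were uridines, though uridines made up 22.3% of the 179 tested positions (two-sided Fisher's exact test, adjusted p = 1.42e-10 over 20 tests). Among those of Xist in cells 18 of 20 were uridines, against 33.2% of 313 tested positions (Fisher's exact test, adjusted p = 8.37e-07). Xist in vitro had 14 of 20 (Fisher's exact test, adjusted p = 0.000795) and 7SK in vitro 11 of 20 (Fisher's exact test, adjusted p = 0.00143). In series A uridines were 3 of 20 (Fisher's exact test, adjusted p = 0.635), and 10 were adenosines, which made up 14.5% of the tested positions (Fisher's exact test, adjusted p = 0.000362).

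In 7SK in cells, series B, the position with the largest range was U164, in the sequence CCGAAUAGAGG with U164 at its centre. Its rate ran from 2.44 per 1000 (95% Wilson interval 2.25 to 2.64) to 36.5 (35.8 to 37.3). U110 followed, from 1.78 (1.57 to 2.02) to 30.8 (30.0 to 31.7) per 1000, and then U63, U180, U41, U155, U181, G64, U54 and U156. U180 and U181 lie side by side in CGGUCUUCGGU and ran from 0.540 to 25.6 and from 0.675 to 22.5 per 1000. G64 was the only guanosine among these 10 positions, and its rate ran from 0.695 to 21.0 per 1000. It lies next to U63, which ran from 2.23 to 28.5, but their highest rates came from different libraries. Those of G64 were in libraries 1 and 2, and those of U63 in libraries 7 and 8. In series A the 10 were, in order, A162, A163, C160, C141, U164, A165, C108, A49, A167 and U63. A162 ran from 0.374 to 27.5 per 1000, A163 from 0.480 to 27.5, C160 from 0.872 to 27.3, C141 from 1.09 to 25.0, A165 from 0.329 to 19.8 and A167 from 0.178 to 16.4. The highest rates at A162, A163, A165 and A167 were all those of library 2, and the next highest were 6.44, 8.60, 5.03 and 4.19 per 1000. For 8 of these 10 positions the range was over 1.5 times that without the library with the highest rate, and for 1 of 10 in series B, G64, where the next highest rate was 9.90 per 1000.

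In 7SK in vitro the 10 were, in order, U30, U63, U54, C80, U41, U53, C154, G9, C160 and U58. U30 ran from 10.2 (8.79 to 11.8) to 147.2 (140.8 to 153.9) per 1000, U54 from 24.5 to 108.4, C80 from 49.1 to 122, U41 from 1.02 to 61.6 and U53 from 8.93 to 59.8. C154 ran from 14.6 to 52.2 per 1000, C160 from 29.8 to 61.6 and U58 from 4.07 to 33.3. The ranges of U54, C154 and C160 were 1.61, 6.11 and 4.09 times those without library 1, which had their highest rates. With the other primer U30 ran from 5.41 to 58.3 per 1000 and came second, behind U63. U63 stood apart by its level. It ended 382 to 475 of each 1000 cDNAs in all 6 libraries, which by the labels include the untreated ones, with a median of 440, and 261.9 to 318 with the other primer, with a median of 283. In cells U63 ended 3.22 to 18.7 per 1000 in series A (median 4.27) and 2.23 to 28.5 in series B (median 6.92), with medians of 1.74 and 2.52 with the other primer. G9 likewise had a median of 28.5 per 1000 in vitro, against 0.339 in series A and 0.595 in series B.

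**Figure D2:**
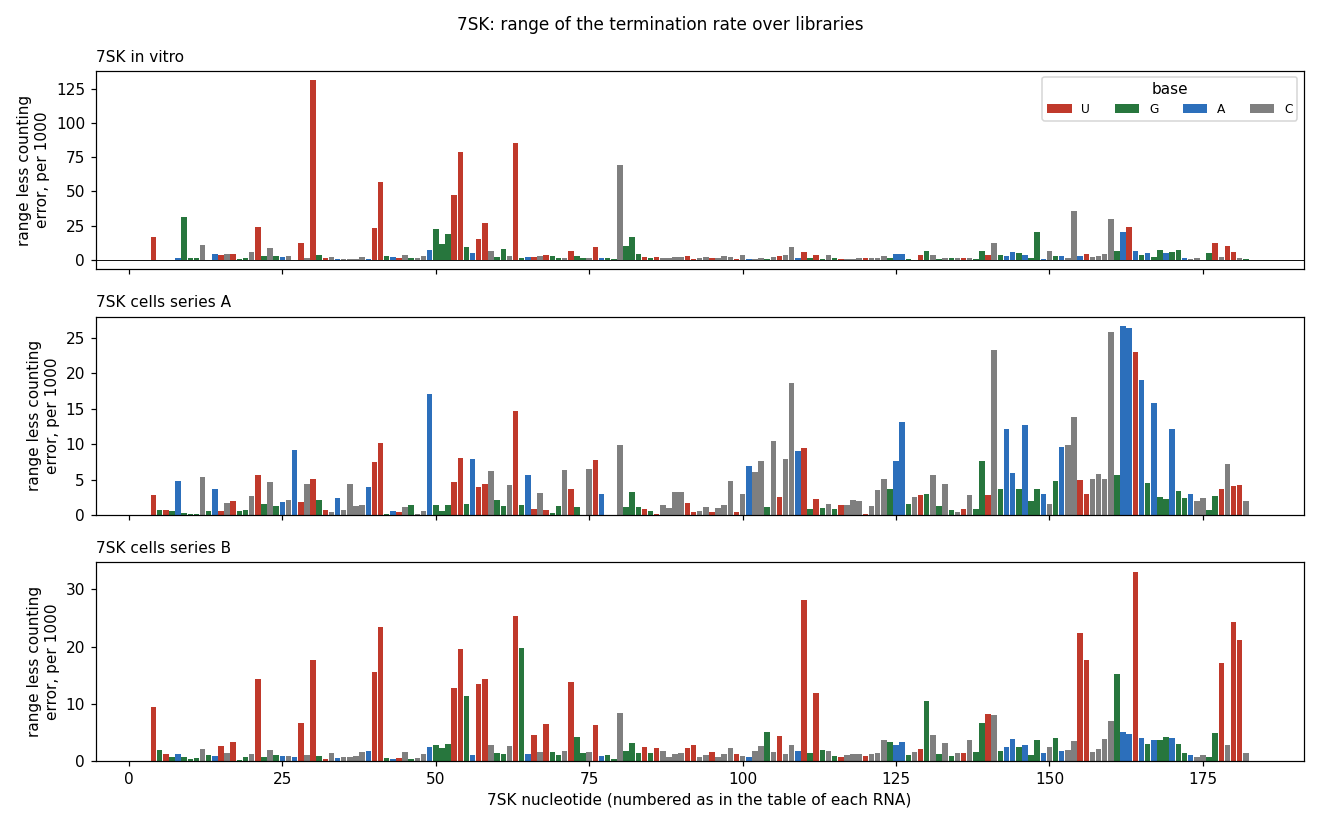
Range of the termination rate over libraries less counting error, per 1000 cDNAs (vertical axis), at each tested nucleotide of 7SK (horizontal axis), coloured by base, in vitro and in both series in cells. The tallest bars are U30 in vitro (131.5), A162 in series A (26.6) and U164 in series B (33.1).

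In Xist in vitro 9 of the 10 positions with the largest range were uridines, and 9 of the 10 were unpaired in the predicted structure. Elsewhere fewer of the 10 were predicted unpaired: 4 in Xist in cells, 5 in 7SK in vitro, 5 in series A and 7 in series B. U63, among the 10 in every 7SK experiment, was predicted paired by the sequence model, which was not checked against a known structure of 7SK. U4841 ran from 8.23 (7.96 to 8.52) to 75.8 (74.9 to 76.6) per 1000, U4770 from 15.2 to 78.5, U4711 from 38.7 to 92.2 and U4794 from 45.9 to 93.6. U4764, U4761, U4754, U4842, C4864 and U4760 followed. C4864 ran from 54.9 to 86.1 per 1000, and its range was 2.11 times that without library 1, where its rate was highest. For Xist in cells all 10 were uridines. U4668 ran from 8.42 (3.28 to 21.4) to 177 (153.9 to 202.9) per 1000, where the lowest value rested on 4 terminations. U4761, in CAUGUUAAUCA, ran from 20.4 (14.1 to 29.3) to 143.9 (134.5 to 153.7) per 1000, U4758 from 23.3 to 143 and U4792 from 15.9 to 122. U4699, U4703, U4794, U4754, U4760 and U4671 completed the list, and the range of U4699 was 1.545 times that without library 6, where its rate was highest.

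**Figure D3:**
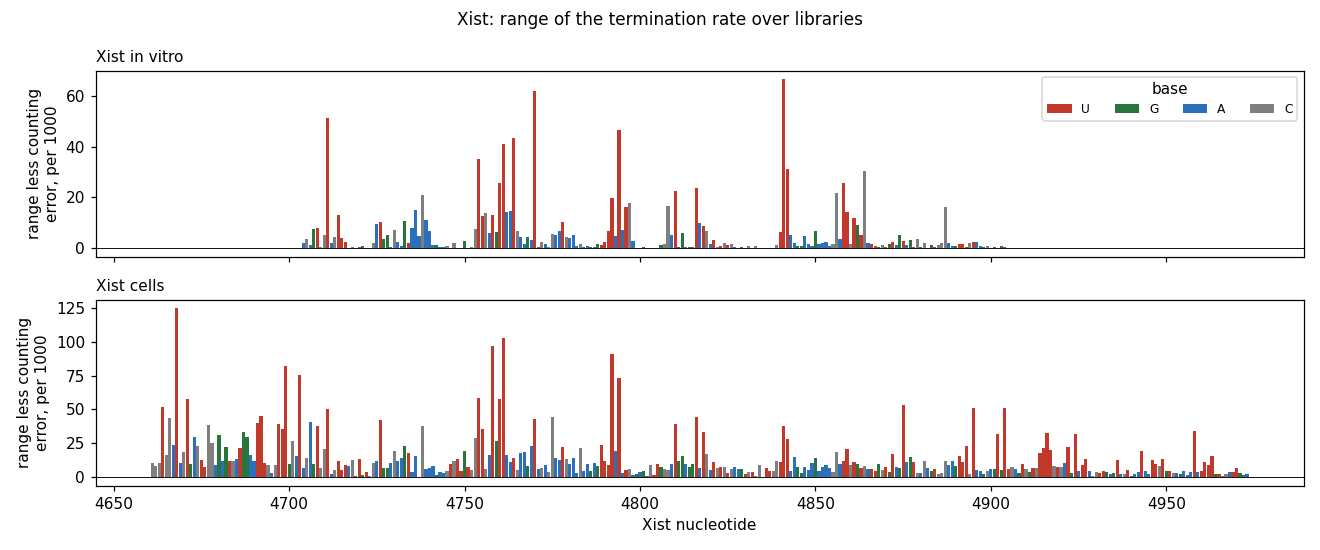
Range of the termination rate over libraries less counting error, per 1000 cDNAs (vertical axis), at each tested nucleotide of Xist (horizontal axis, Xist numbering), coloured by base, in vitro and in cells. U4841 in vitro reached 66.7, and U4668 and U4761 in cells reached 125 and 103.

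The design implies a comparison of paired with unpaired bases, since the reagents need a free pairing face. Structures were predicted from sequence and not measured. In the 7SK models the 5′ end pairs with bases in the 3′ part. The region named 5′ hairpin below is therefore not a single hairpin in them, and pairing calls there depend on that fold. In Xist in vitro the median range was 19.3 per 1000 at 20 uridines predicted unpaired and 0.983 at 42 predicted paired (permutation test, p = 3e-05, adjusted p = 0.00015 over 10 comparisons). With positions down to 60 nt from the primer tested, the difference went from 18.3 to 9.27 per 1000. The medians for Xist in cells were 20.5 at 45 unpaired and 10.7 at 59 paired uridines (permutation test, adjusted p = 0.0136). That difference of 9.84 per 1000 fell short of the threshold in the permutation test at a coverage of at least 1000 (4.72, adjusted p = 0.0631), with the other primer (0.914, adjusted p = 0.492), on a log2 scale (0.39, adjusted p = 0.247) and with stops on the last copied base (2.09, adjusted p = 0.193).

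For 7SK in cells the medians at 21 unpaired and 19 paired uridines were 13.8 and 3.23 per 1000 in series B (permutation test, adjusted p = 0.0479) and 4.15 and 1.65 in series A (permutation test, adjusted p = 0.0410). Both lost the threshold when 20 positions at each end were left out (permutation test, adjusted p = 0.290 and 0.234). They also lost it with stops on the last copied base, where the differences of 10.5 and 2.50 became 0.359 and 1.45, and on a log2 scale, where they were 0.44 and -0.32. Leaving out library 2 of series B gave an adjusted p of 0.0877, and leaving out library 6 of series A gave 0.0690. In 7SK in vitro 20 unpaired uridines had 5.78 per 1000 and 19 paired uridines 3.50 (permutation test, adjusted p = 0.301). With base pair probability as the structure model that difference of 2.28 was 9.22, past the threshold (permutation test, adjusted p = 0.0116), and with stops on the last copied base it was -0.0506.

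With guanosines added, unpaired positions exceeded paired ones in all 5 experiments, with stops placed as in the table. This comparison mixes pairing with base, since uridines made up more of the unpaired than of the paired positions. In series B they were 21 of 32 unpaired and 19 of 62 paired positions, and 20 of 31 and 19 of 63 in 7SK in vitro. Median ranges were larger at uridines than at guanosines (7.41 against 1.41 per 1000 in series B), so pairing and base were not separated here. The medians were 14.2 and 0.933 per 1000 for Xist in vitro (permutation test, adjusted p = 0.0001), 5.33 and 2.25 for 7SK in vitro (0.0142), 2.79 and 1.36 for series A (0.0136), 6.57 and 1.81 for series B (0.000833) and 16.2 and 9.20 for Xist in cells (0.00288). The series A difference of 1.43 was 0.768 without library 2, 1.72 with the other primer (permutation test, adjusted p = 0.0853) and -0.35 on a log2 scale (permutation test, adjusted p = 0.405). On that scale the Xist difference in cells was 0.37 (permutation test, adjusted p = 0.167). The 7SK in vitro result lost the threshold of the permutation test without library 1 (adjusted p = 0.0681), without library 6 (adjusted p = 0.173) and with 20 positions left out at each end (adjusted p = 0.359). With stops on the last copied base the difference changed sign in 7SK in vitro (-1.12) and series B (-0.276) and fell short of the threshold in series A (1.56) and Xist in cells (2.09).

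By region, the uridines of 7SK in series B had a median range of 6.29 per 1000 in the 5′ hairpin (27 uridines) and 17.1 from there to nucleotide 182, the last tested (13 uridines). Other bases had 1.20 and 2.41 in those regions. In series A the uridine medians were 1.95 and 3.04 against 1.47 and 3.62 for other bases, and in vitro they were 4.07 and 4.02 against 1.78 and 2.40. The remaining 7SK regions, with the pseudouridine known at U250, lie under or too near the primer and were not analysed here. For Xist in cells the uridine medians in the first, middle and last part of the tested stretch were 28.5, 10.8 and 11.7 per 1000 (11.4, 7.22 and 3.70 for other bases). In vitro they were 8.04, 1.91 and 1.64 (3.59, 0.9751 and 1.63 for other bases). These regional values were not tested.

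Profiles were compared between experiments across positions, which are not independent replicates, so no p-value is given. Over 177 aligned positions of 7SK the range in series B correlated with that in vitro with Pearson's r of 0.545 and Spearman's rho of 0.650, and among 39 uridines rho was 0.847. Of the 20 positions with the largest range in each, 10 were shared, where 2.26 would be shared by chance. They were U21, U30, U40, U41, U53, U54, U57, U58, U63 and U163, in the numbering of the RNA used in vitro. Series A and series B shared 3 of 20 (U41, U63 and U164), against 2.23 by chance, with r of 0.323 and rho of 0.540 over 179 positions. Among their 40 uridines rho was 0.862. Series A and the in vitro RNA shared 7 of 20, against 2.26 by chance, with r of 0.313 and rho of 0.473. Xist in cells and in vitro had r of 0.571 and rho of 0.502 over 202 positions and shared 11 of 20, against 1.98 by chance. The shared Xist positions included U4711, U4754, U4760, U4761, U4770, U4792, U4794 and U4841. On the log2 scale the correlations were lower, with r of 0.368 for series B and in vitro, 0.07 for Xist, -0.016 for series A and B and -0.119 for series A and in vitro. The median rates themselves had rho of 0.764 for series B and in vitro, 0.573 for Xist, 0.892 for series A and B and 0.795 for series A and in vitro. A range can grow with the rate, so shared ranges were not separated from shared termination levels. The numbers expected by chance take no account of such levels.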

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

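The tests in this part were all chosen after the values had been seen. Mutation fractions are used in no comparison of the results, and no library is known to be untreated, so a position was listed when its highest mutation percentage reached 2% and either 5 times the median over libraries or 10% in every library. The highest value of each listed position lies above the limit that a count of 0 allows at their depth.

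In Xist in cells, C4674 was read as another base in 12.8% to 26.6% of reads in all 10 libraries, with a median of 20.9% and at least 180 reads. The substitution was C4674G, counted in Xist numbering, in 99.1% of the mismatched calls. A strain or allele difference from the reference sequence could give a single base nearly all the calls (99.1%) and put all 10 libraries above their limit. A difference carried by all of the RNA is argued against by the level, at most 26.6% of reads. The percentage also differed between libraries. Libraries 5, 6 and 9 had 12.8%, 15.5% and 12.8%, with Wilson intervals reaching at most 19.64%. Libraries 1, 2 and 4 had 26.6%, 23.2% and 25.7%, with intervals from 21.2% up. Such intervals cover counting error only, and amplified reads are not independent molecules, so an equal share in every library is not excluded. Misreading at a base modified by a reagent is argued against by the lowest library at 12.8%, since by the labels 2 of the 10 libraries were untreated. Poor base calls in this stretch are argued against by the 10 neighbouring positions, which reached at most 0.929%. No genotype of the cells was used here, so a difference carried by part of the RNA stays open, whether or not its share varies between libraries.

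In series B of 7SK in cells, library 6 had mismatches at U53 in 4.36% of reads and at U54 in 4.75% with the primer nearer the 5′ end, where the medians over 12 libraries were 0.0454% and 0.0349%. A base difference carried by the RNA itself is argued against by the primer nearer the 3′ end, with which U53 in the same library had 0.249% (95% Wilson interval 0.228% to 0.271%), although library 6 was the highest of the 12 with that primer too. The medians there were 0.0567% at U53 and 0.0432% at U54, where library 6 had 0.128%. Early amplification of one molecule is argued against by the calls, since the leading base took 48.1% of the mismatches at U53. No explanation tested here accounts for it, and no biological one was tested.

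In series A of 7SK in cells, C12 had 5.59% mismatches in library 1 and 5.08% in library 2 with the primer nearer the 3′ end, against a median of 0.548% over 8 libraries. With the other primer it had 5.20% and 4.33% there, against a median of 0.550%. The other 6 libraries had at most 0.571% and 0.625%. Libraries 1 and 2 are also those with the highest mean adenosine termination rates of the series, 3.94 and 9.84 per 1000. No explanation was tested. In Xist in cells, C4665 reached 2.66% in library 6 (7 of 263 reads, 95% Wilson interval 1.29% to 5.39%), with a median of 0.0397% over 10 libraries, 5 libraries at 0 and as few as 131 reads.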

How the results depend on the processing

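The log2 scale, the range without subtraction of counting error, 60 nt from the primer, the other primer and each library left out were chosen after seeing the data. The other alternatives were fixed before. No paired analysis was possible because the table's libraries carry no replicate letter and no treatment. The planned count models, TMM and DESeq2 fits, fits on the compared groups alone, rate ratio thresholds, pseudocounts and replicates left out per group were not run for the same reason. Differences below are medians of the range per 1000, first minus second class, for uridine (U), guanosine (G) or both against adenosine and cytidine, or for unpaired against paired bases. Of 212 values under alternatives other than leaving out a library, 167 kept direction and side of the threshold, 19 lost the threshold, 6 gained it and 20 changed sign. Values that changed sign are counted only as such, and some of them also crossed the threshold. A coverage of at least 1, no subtraction of counting error, 60 nt from the primer and folding at 25 °C changed none of the calls. Unless a reason is given, the cause was not tested.

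Placing stops on the last copied base moves each value to the neighbouring base, which is the cause by construction. U against A and C then gave -0.129 for Xist in vitro, 0.352 for 7SK in vitro, 2.30 for series A, 0.307 for series B and 1.29 for Xist in cells. G gave 2.16 for 7SK in vitro, 1.41 for series A, 1.44 for series B and 1.77 for Xist in cells. Both together gave 1.62, 1.68 and 1.57 for 7SK in vitro, series A and Xist in cells. Unpaired against paired U gave -0.0506, 1.45, 0.359 and 2.09 for 7SK in vitro, series A, series B and Xist in cells, and U and G -1.12, 1.56, -0.276 and 2.09.

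On the log2 scale U against A and C gave 0.17 for Xist in vitro and -1.32 for series A, both past the threshold, and -0.0335 for Xist in cells. G gave 0.0185 for Xist in vitro and 0.029 for Xist in cells, and U and G 0.0826 for Xist in vitro, 0.33 for 7SK in vitro and -0.024 for Xist in cells. Unpaired against paired gave -0.32 for U and -0.35 for U and G in series A, 0.44 for U in series B, and 0.39 for U and 0.37 for U and G in Xist in cells. Adjusted p for U against A and C ranged over these alternatives from 3.75e-05 to 0.356 in series B and from 3.75e-05 to 0.847 in Xist in cells.

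The other primer tests another stretch, nucleotides 4 to 74 of 7SK and, for Xist in cells, one that shares 134 positions. Primer and stretch were therefore not separated. With the other primer, G against A and C gave -0.450 for 7SK in vitro and 0.485 for Xist in cells. In series A, U gave 2.30, both bases -0.910 and unpaired U and G 1.72. Unpaired U in Xist in cells gave 0.914. With 20 positions left out at each end, both bases gave 0.199 for Xist in vitro, and unpaired against paired gave 0.727 for U and G in 7SK in vitro, 1.80 for U in series A and 6.98 for U in series B. Fewer positions were tested there. A coverage of at least 1000 left 4.72 for unpaired U in Xist in cells, again with fewer positions. That minimum also removes the 5′ part of the stretch, where uridine ranges were larger, so depth and region were not separated. Base pair probability gave 9.22 for unpaired U in 7SK in vitro, now past the threshold.

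With each library left out in turn, 5 of 210 values changed sign and are counted only as such, whether or not they crossed the threshold. Of the others, 4 lost the threshold, 2 gained it and the rest kept both. U against A and C ranged from -0.00742 to 0.608 for Xist in vitro and from -1.83 to 0.768 for series A, the latter without library 2. G ranged from -0.470 to 0.602 for 7SK in vitro and from -0.175 to 0.491 for series B, the latter without library 9, past the threshold (adjusted p = 0.0415, permutation test). U and G ranged from 0.240 to 1.13 for 7SK in vitro, past the threshold without library 1 or 6. Unpaired against paired U and G ranged from 1.21 to 3.72 for 7SK in vitro, and U from 1.97 to 3.11 for series A and from 9.37 to 10.6 for series B. U and G against A and C in series B rose to 1.61 without library 9, and unpaired U and G in series A was 0.768 without library 2.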

Other observations

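The tests of explanations in this part were chosen after the values had been seen. Libraries carry no treatment here, and the values are given by the table's library number.

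The ratio of the mean termination rate at uridine to that at adenosine and cytidine separated libraries within experiments. In series B it was 0.808, 1.14, 1.12, 1.04, 2.42, 2.49, 5.44, 5.16, 1.08, 1.35, 2.35 and 3.25 for libraries 1 to 12. In Xist in cells it was 0.782, 0.848, 2.11, 3.32, 5.24, 6.04, 1.02, 1.09, 2.03 and 3.23 for libraries 1 to 10. In series A it was 0.558, 0.399, 3.05, 2.62, 4.32, 4.43, 1.55 and 1.34 for libraries 1 to 8. The values of libraries 1 and 2 of series A lay below 1, where the mean adenosine rates were 3.94 and 9.84 per 1000. The other 6 libraries of that series had adenosine rates of 0.388, 0.708, 1.21, 1.24, 1.42 and 1.29 per 1000. In Xist in vitro the ratio was 0.675, 0.684, 1.86, 1.92, 1.12 and 1.12 for libraries 1 to 6, and in 7SK in vitro 4.12, 4.74, 2.59, 2.79, 2.91 and 2.45. Without U63 the 7SK in vitro ratio was 2.55, 2.84, 1.28, 1.24, 0.738 and 0.672.

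The larger range at uridines was weighed against technical explanations. If rates at all bases rose and fell in proportion, the ratio of uridine to adenosine and cytidine would be equal in all libraries within counting error. Its highest value was 6.73 times its lowest in series B, 7.72 times in Xist in cells and 1.93 times in 7SK in vitro (4.22 times without U63), with counting intervals apart, so a factor common to all bases is argued against in all 3. If each position varied in proportion to its own level, uridine would have no larger range on a log2 scale, a condition added once both results were known. The log2 difference was 1.27 in series B and 0.71 in 7SK in vitro, both past the threshold, which argues against it there. In Xist in cells it was -0.03 (permutation test, adjusted p = 0.847), so variation in proportion to each position's level stays open there. A single library is argued against as well: with each library left out in turn, the lowest difference between uridines and adenosines and cytidines was 5.43 per 1000 in series B, 5.00 in Xist in cells and 1.75 in 7SK in vitro, each past the threshold. Reaction of uridines with the carbodiimides is a hypothesis that stays open, since it was not tested by treatment, and differences between preparations stay open too.

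Libraries were also compared by their profile over positions, as the log2 rate less its mean over libraries. In Xist in vitro libraries 1 and 2 correlated with r of 0.845, libraries 3 and 4 with 0.872 and libraries 5 and 6 with 0.777, while the next closest library had at most 0.102. In 7SK in vitro the closest pairs were the same, with 0.247, 0.0808 and 0.0782. In series A the closest to libraries 1 to 8 were libraries 2, 1, 4, 6, 6, 5, 8 and 7, with r of 0.433, 0.433, 0.447, 0.503, 0.840, 0.840, 0.640 and 0.640. In series B the closest to libraries 1 to 12 were libraries 2, 1, 4, 3, 8, 7, 8, 7, 3, 4, 12 and 8, with r of 0.649, 0.649, 0.771, 0.771, 0.664, 0.587, 0.929, 0.929, 0.508, 0.668, 0.418 and 0.621. In Xist in cells the closest to libraries 1 to 10 were libraries 2, 8, 6, 6, 10, 4, 2, 2, 2 and 5, with r of 0.148, 0.309, -0.0021, 0.157, 0.137, 0.157, 0.215, 0.309, 0.0877 and 0.137.

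In series B the median mutation fraction within 20 nt of the primer coordinate was 4.80, 4.85, 5.44, 5.49, 4.97, 5.39, 4.93, 4.52, 1.87, 2.48, 2.20 and 1.96 per 1000 for libraries 1 to 12. Over the tested template positions it was 0.652, 0.659, 0.665, 0.634, 0.629, 0.685, 0.672, 0.642, 0.783, 0.829, 0.799 and 0.807 per 1000. Libraries 9 to 12 thus had the lower values near the primer and the higher ones on the template. With the same primer the template median at adenosines ran from 8.54 to 12.2 per 1000 over the libraries of series A and from 0.682 to 0.856 over those of series B. The other bases were higher in series A too. Cytidines had 5.06 to 7.54 against 0.548 to 0.905, guanosines 4.05 to 5.03 against 0.654 to 0.981 and uridines 5.08 to 6.52 against 0.508 to 0.660.

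Both primers gave rates at the same bases in the same libraries. Over 71 shared positions of 7SK their rates correlated with a median Spearman's rho of 0.839 in vitro, 0.745 in series A and 0.751 in series B, and over 134 positions of Xist in cells with 0.344. The median rate with the primer nearer the 3′ end of 7SK was 2.67 times that with the other primer in vitro, 1.69 times in series A and 2.08 times in series B.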
